A study of Mus musculus with 6 samples.

How the data were processed

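The series holds 6 samples of CD8+ pMel-1 T cells, 3 DC-primed and 3 B cell-primed, cultured for 3 days. Per the labels' protocols, total RNA was extracted with the mirVana kit and treated with DNase I, poly(A) tails were added, cDNA was made from oligo-dT primers carrying a universal tag, and each miRNA was amplified with its own forward primer and a universal reverse primer. Poly(A) tailing and a single forward primer distinguish close family members poorly, so near-identical miRNAs, such as miR-23a and miR-23b or miR-17, miR-106a and miR-20a, can share signal. Samples were grouped by their titles, which also give the round. The labels do not say whether rounds came from separate animals, so p-values measure only the spread between these samples.

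Per the file headers, 1 deposited table holds raw Ct values and another the authors' dCt values. The names of these 2 files state the reverse of their headers, and the values match the headers. The Ct table has 350 miRNA assays, 8 wells of RNY3, 8 of snoRD47, 9 of cel-mir-67 and 1 of cel-mir-356. The dCt table has 345 miRNA assays, of which 42 carry human names, with 5 left out. Its values are on a log2 scale with the sign turned, made by the authors as Ct minus 1 number per sample, which per the file headers is the geometric mean of the sample's Ct values. The number found from the values was 0.332 to 0.658 cycles below the geometric mean of all deposited Ct values, so the set of assays behind it was not recovered. The authors filled in 10 missing Ct values, all equal to the mean of the group's other 2 samples within 0.01 cycles. Apart from miR-23a and miR-23b, Ct minus that number gave the deposited dCt within 0.02 cycles. The authors' p-value is from a two-tailed paired test on dCt, per the file headers, and was recomputed to within 1.29e-09. The authors' fold change is the ratio of DC-primed over B cell-primed, 2 to the power of minus ddCt. The instrument and the rule for calling Ct are not given in the sources used here.

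Here dCt was turned so that higher means more miRNA. An assay was tested if its raw Ct was present and below 35 in all 6 samples, which left 274 assays and left out 71. DC-primed sample 3, with 280 assays below 35, decided most of these exclusions, miR-223, miR-146b and miR-183 among them. The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no block, two-sided), DC-primed minus B cell-primed, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are limma's moderated ones, and SD is over the 3 samples of a group. Lists of miRNAs were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 19 of 21 lists with at least 3 tested assays; fry and an estimated correlation were run beside it. Single values per sample were compared by exact permutation, where 3 samples against 3 allow no p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

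The lists, fixed before the data were examined, were the miR-17/miR-92a cluster and its paralogs, miRNAs raised and lowered by T cell activation, NF-kappaB-responsive miRNAs, the let-7, miR-29, miR-30, miR-181, miR-15 and miR-16, miR-34 and miR-449, and miR-200 families, the miR-23/miR-27/miR-24 and miR-183/miR-96/miR-182 clusters, the imprinted Dlk1-Dio3 locus, the mouse Sfmbt2 intron cluster, the miR-290 and miR-302 clusters, and markers of myeloid and dendritic cells, B cells, erythroid cells, stromal and endothelial cells and other tissues. Human-named and star-strand assays counted as members of the list of their name. Named miRNAs were chosen by a rule fixed at the same time: the 10 largest differences in each direction among called assays, filled up with the largest differences that had the same sign in all 3 rounds; 20 miRNAs named in advance; the largest and smallest member of each tested list; and assays detected in 1 group only. miRNAs named beyond these were chosen after their values were seen. They are miR-222 and miR-146b, the members of the miR-17/miR-92a, myeloid and miR-23/miR-27/miR-24 lists that are not the largest or smallest, and the members of the miR-183/miR-96/miR-182 and erythroid lists. No coordinates are given, since the files name no genome build.

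The round numbers come from the sample titles. Deviations of same-round samples from their group means correlated across assays at 0.16, 0.14 and 0.46 for rounds 1, 2 and 3. DC-primed sample 1 correlated more with B cell-primed sample 2, at 0.33, so these correlations alone do not establish the pairing. The rounds were taken to pair the samples for the differences by round and the block alternative, as the authors' paired test does. The main limma fit, camera and the permutation tests did not use the pairing. Rank correlations of levels across assays were 0.90 to 0.93 within B cell-primed, 0.64 to 0.83 within DC-primed and 0.74 to 0.86 between the groups.

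Alternatives fixed before the data were examined were 4 normalizations, 4 detection limits, the round as a block, other variance models, a threshold of 0.1, other list tests, a 1.5-fold size, and leaving out each sample or round. Values from the Ct table, RNY3 and snoRD47 as reference, the methods' paired test, lists without star strands or human-named assays, and DC-primed sample 3 or round 3 left out of both filter and fit were added after seeing the data. The fits were tested on simulated data: with the 274 assays' spread, limma called 1.25%, 8.75% and 70.5% of assays shifted by 1, 2 and 4 on the log2 scale, and 0.35% of unshifted assays. The design therefore finds few differences of 2 log2 units or less.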

Results

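MicroRNA levels were measured by SYBR Green quantitative RT-PCR in mouse CD8+ pMel-1 T cells, which carry a transgenic T cell receptor for the melanoma antigen gp100. The cells had been primed in vitro for 3 days. Mature bone marrow-derived dendritic cells treated with lipopolysaccharide primed 3 samples (DC-primed, the test group), and splenic B cells loaded with a gp100 peptide primed the other 3 (B cell-primed, the control group). Each of 3 rounds gave 1 sample of each group. Levels are given on the log2 scale as minus dCt, so that 1 unit is a 2-fold difference and a higher value means more miRNA.

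Of 350 miRNA assays, 337, 327 and 280 had a threshold cycle (Ct) below 35 in the DC-primed samples of rounds 1, 2 and 3, against 341, 336 and 336 in the B cell-primed samples. The group means were 314.67 ± 30.4 and 337.67 ± 2.89 (SD, n = 3 each), a difference of -23 assays that was within the spread (two-sided exact permutation p = 0.3, the smallest possible being 0.1). That test ignores the rounds, and the DC-primed count was the lower one in every round. Without DC-primed sample 3 the difference was -5.67 assays. That sample had the latest Ct values, with a mean of 30.5 over the tested assays, against 26.3 and 28.4 in the other DC-primed samples and 26.4, 27.2 and 27.6 in the B cell-primed samples. On the authors' scale the median level of the 274 assays tested was -0.44 ± 0.24 in DC-primed and -0.48 ± 0.19 in B cell-primed cells (n = 3 each), a difference of 0.03 (exact permutation p = 0.9). Without normalization the difference of these medians was -1.30, and relative to the small RNAs RNY3 and snoRD47 it was 1.26, so the differences below are relative to the authors' per-sample number. Positive differences under 1.33 change sign in the first, and negative ones closer to 0 than 1.23 in the second. Wells of 1 sample scattered widely, with an SD of 1.59 to 2.80 cycles for RNY3 and 2.97 to 6.05 for snoRD47. The scaling to these 2 RNAs is therefore itself uncertain.

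The comparison asked which miRNAs differ in CD8+ T cells according to the cell that primed them. Among the 274 tested assays, the largest differences toward DC-primed cells with 1 sign in every round were those of miR-147, which is induced by Toll-like receptor signalling in macrophages, at 3.25 ± 1.17 (SE), and of miR-21, an abundant miRNA raised by T cell activation, at 3.19 ± 1.26. miR-21 reached a level of 10.1 ± 2.77 in DC-primed and 6.95 ± 0.51 in B cell-primed cells (SD, n = 3 each). The miR-147 difference was 1.80 without DC-primed sample 1, and that of miR-21 was 1.80 without DC-primed sample 3. Apart from miR-23a and miR-23b, for which the 2 deposited tables disagree (below), the largest toward B cell-primed cells were miR-805 at -3.71 ± 0.83 (SE), miR-18a at -3.62 ± 1.22, miR-18a* from the other strand of the same hairpin at -3.25 ± 0.74, miR-677 at -3.24 ± 0.95 and miR-298 at -3.00 ± 0.71. The miR-298 difference was the most even, at -3.02, -2.90 and -3.06 in the 3 rounds. None of these assays passed the test: limma called 0 of 274 assays at an adjusted p under 0.05, with a smallest adjusted p of 0.228, and 24 had an unadjusted p under 0.05 where 13.7 are expected by chance. Of those 24, 4 were higher and 20 lower in DC-primed cells; the count was 58 without DC-primed sample 1 (25 higher and 33 lower), 42 without DC-primed sample 3 (21 and 21) and 11 to 15 without any other single sample. The direction also depended on the scaling, with 0 higher and 18 lower without normalization and 14 higher and 0 lower relative to RNY3 and snoRD47. With the round as a block limma also called 0, with a smallest adjusted p of 0.0522, shared by miR-298, miR-805, miR-18a, miR-18a*, miR-677, miR-23a and miR-23b, and 33 at an unadjusted p under 0.05 (12 higher and 21 lower).

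Further assays toward DC-primed cells that missed the threshold were miR-99b at 2.54, miR-10a at 2.00, miR-24-1* at 1.79, let-7b at 1.56 and miR-150* at 1.5, with the human-named assays miR-424* at 1.87, miR-20b* at 1.73 and miR-504 at 1.54. Toward B cell-primed cells they were miR-374 at -2.72, miR-296-5p, which is encoded beside miR-298, at -2.51, and the human-named miR-520g at -2.69. Several of these moved far over the alternatives. miR-424* ranged from -0.81 to 4.32, miR-504 from 0.06 to 2.77, miR-10a from 0.67 to 3.22 and miR-296-5p from -3.84 to -1.28. miR-520g belongs to a primate cluster, and 9 of the 11 assays for that cluster had a Ct below 35 in all 6 mouse samples, so a Ct below 35 alone does not identify the RNA. miR-411 alone was below Ct 35 in all 3 B cell-primed and no DC-primed samples. Its B cell-primed level of -7.33 ± 0.17 lay below the limit of -6.63 that applied in the DC-primed samples, so no fold is given.

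In size, 88 of the 274 assays differed by 1 or more on the log2 scale (46 higher and 42 lower in DC-primed cells), and 50 of these had the same sign in all 3 rounds, 20 higher and 30 lower. Over all sizes 70 of 274 assays (25.6%) had the same sign in every round, where 25% is expected by chance. Without normalization the count of 50 was 101 with 0 higher, and relative to RNY3 and snoRD47 it was 101 with 97 higher. With a Ct limit of 32 it was 28, with 13 higher.

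Among the settings run, only leaving out DC-primed sample 3 gave calls. With the detection filter still over all 6 samples limma called 2 assays, miR-222 higher and miR-805 lower. With that sample left out of the filter too, limma called 5 assays: miR-223, abundant in myeloid cells, was 8.68 ± 1.11 (SE) higher in DC-primed cells (adjusted p = 0.00376), miR-146b was 6.92 ± 0.95 higher (0.00376), miR-222 was 4.98 ± 0.96 higher (0.0288), miR-100 was 4.04 ± 0.84 higher (0.042) and miR-805 differed by -4.38 ± 0.81 (0.0286). miR-223 had a Ct of 20.8 and 27.2 in DC-primed samples 1 and 2, 36.99 in DC-primed sample 3, and 32.1, 32.4 and 32.7 in the B cell-primed samples. With both samples of round 3 left out, limma called 0 of 321 assays, with differences of 6.07 for miR-146b (adjusted p = 0.059) and 8.85 for miR-223 (0.0705), about as large but from 4 samples.

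**Figure D1:**
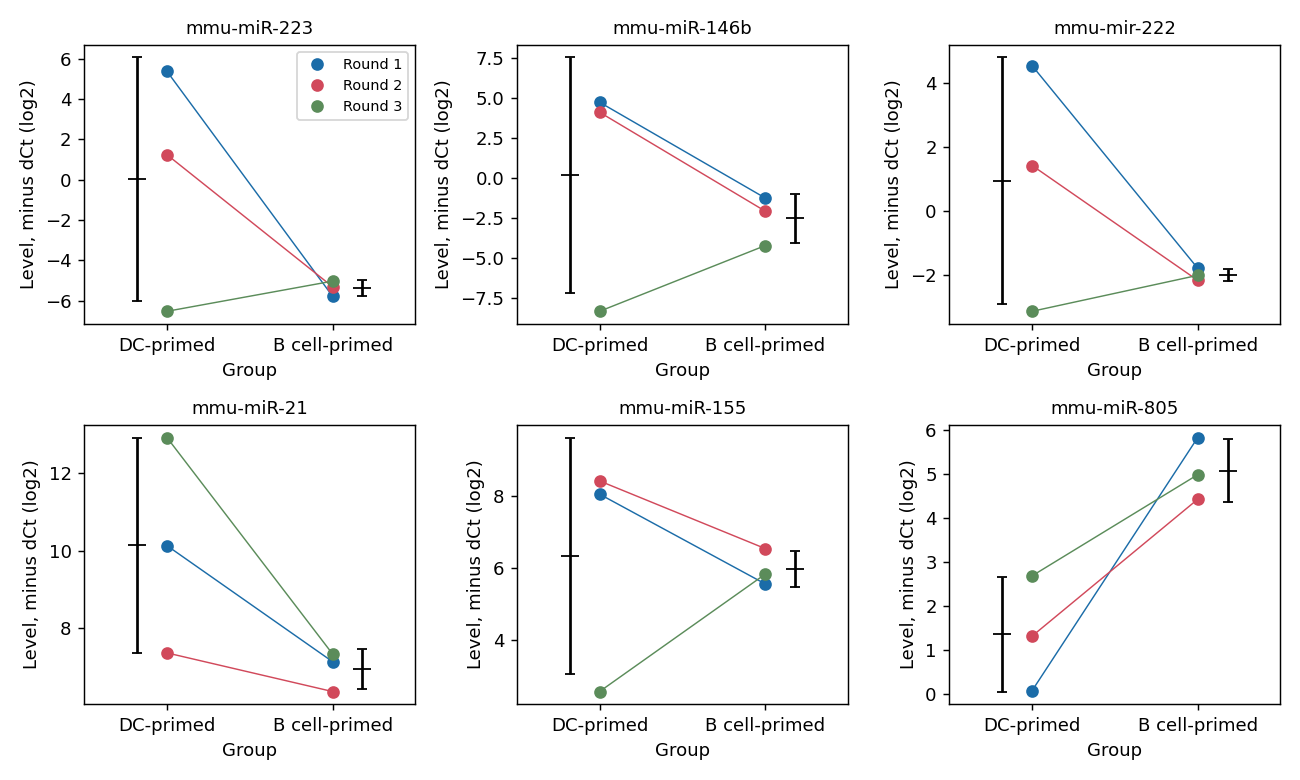
Level (minus dCt, log2) of 6 miRNAs in each DC-primed and B cell-primed sample; points and lines are rounds, and black marks with bars are group means with SD (n = 3). The round 3 DC-primed sample lies below its B cell-primed partner for miR-223, miR-146b, miR-222 and miR-155, whereas miR-21 is higher and miR-805 lower in the DC-primed sample of every round.

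Of 19 lists tested, camera called 2, 1 in each direction. The number was 6 without DC-primed sample 3, 5 without B cell-primed sample 1, 4 without B cell-primed sample 2 and 5 without round 3. Adjusted over the list alone, members passed in 3 of the 19 lists.

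Members of the miR-17/miR-92a cluster and its paralogs, which promote lymphocyte proliferation, were lower as a group in DC-primed cells. Of 17 tested assays 14 were lower and 3 higher, with a median difference of -1.48 (limma's camera with a preset correlation, adjusted p = 4.06e-05 over 19 lists); adjusted p = 0.347 with an estimated correlation, so the call was lost. The 17 assays include both strands of the miR-18a and miR-17 hairpins, and the near-identical miR-17, miR-20a and miR-106a can share signal. They are therefore not 17 independent miRNAs. The 4 largest differences were those of miR-18a, miR-18a*, miR-19b at -2.92 ± 1.45 (SE) and miR-20a at -2.47 ± 0.90, with miR-17 at -2.13 ± 0.82. On the other side were miR-92a at 0.80 ± 1.49 and the human-named miR-20b* at 1.73 ± 1.10. No member passed over all assays, and 1, miR-18a*, passed adjusted over the list alone, at 0.034 (with the round as a block 2, miR-18a and miR-18a*). The list median was -0.891, -1.985 and -1.005 in rounds 1, 2 and 3. Members varied between rounds: miR-18a differed by -0.96, -6.27 and -3.61, miR-18a* by -1.78, -3.34 and -4.62, miR-17 by -0.18, -3.58 and -2.62, miR-20a by -0.22, -3.92 and -3.25, and miR-19b by 2.13, -5.32 and -5.57. The list's median was negative under every scaling, at -2.81 without normalization and -0.25 relative to RNY3 and snoRD47.

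Markers of myeloid and dendritic cells were higher as a group in DC-primed cells, with 8 of 9 tested assays higher and a median difference of 1.77 (camera adjusted p = 0.022); adjusted p = 0.347 with an estimated correlation, so this call was lost too. The 9 assays include both strands of the miR-22, miR-99b and miR-125a hairpins, so they are not 9 independent miRNAs. The largest members were miR-99b at 2.54 ± 1.08 (SE), miR-22 at 2.53 ± 1.47 and miR-125a-5p at 2.08 ± 1.11, and the smallest was miR-99b* at -0.05 ± 0.67. No member passed over all assays or adjusted over the list alone. The difference was largest in round 1, where miR-22 was at 6.97, miR-99b at 5.07 and miR-125a-5p at 3.98. Without DC-primed sample 1 the list was not called (median 0.88, adjusted p = 0.25), nor with both samples of round 1 left out (1.12, 0.378), with a Ct limit of 32 (1.87, 0.142) or after quantile normalization (1.15, 0.0656). The median was 0.27 without DC-primed sample 3, 0.71 without B cell-primed sample 1 and 0.89 without B cell-primed sample 2, each still called. The B cell-associated list had a median of 0.73 and was not called (camera adjusted p = 0.204), with miR-150* at 1.5 and miR-148a* at -0.15. It shares miR-150 with the list lowered by T cell activation and miR-34a with the myeloid list, so it does not mark B cells alone.

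**Figure D2:**
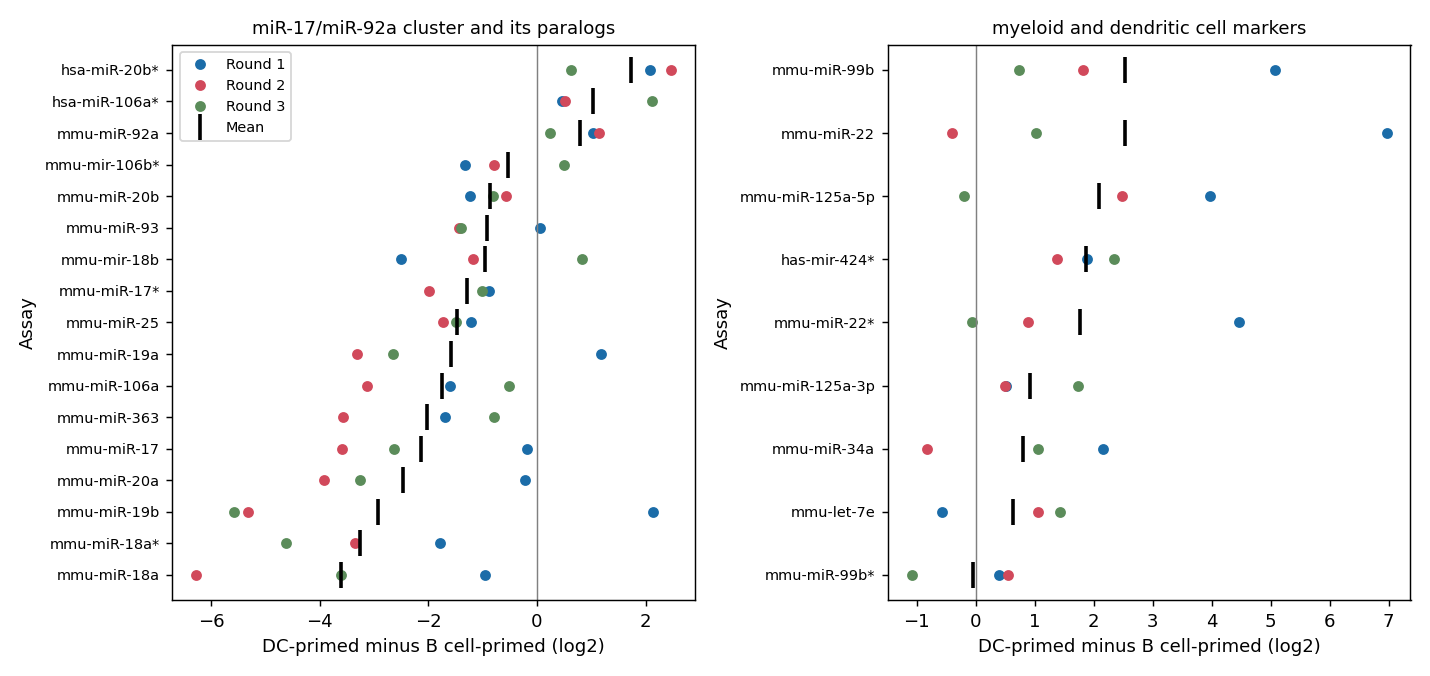
DC-primed minus B cell-primed difference (log2) of each tested assay of the 2 lists called by camera; coloured points are rounds and black bars are means over the 3 rounds. In the left panel 14 of 17 means lie below 0, and in the right panel 8 of 9 lie above 0 with the largest values in round 1.

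miRNAs raised by T cell activation were mixed, with 8 of 20 tested assays higher and 12 lower, a median of -0.47 and no call (camera adjusted p = 0.0656). Camera called the list lower without DC-primed sample 1 (0.031), B cell-primed sample 1 (0.0379) or both samples of round 1 (0.0259), and with more assays tested at a Ct limit of 38 (median -1.29, 0.00343) or with no filter (-1.21, 0.0071). Its lower members included those shared with the miR-17/miR-92a list, as well as miR-182 at -2.19 ± 0.78 (SE) and miR-31 at -1.37 ± 0.90. miR-155, required for effector responses of CD8+ T cells, differed by 0.37 ± 1.43 (95% confidence interval -2.90 to 3.64), with 2.49, 1.88 and -3.25 in the 3 rounds. miR-146a differed by 0.62, miR-210 by 0.60 and miR-221 by 0.58, and none passed. Over the list alone 1 member passed, miR-18a*, and with the round as a block 3 did, miR-18a*, miR-18a and miR-21. The NF-kappaB-responsive list had a median of 0.74 (adjusted p = 0.0889, and called higher without B cell-primed sample 1, at 0.0379, with no filter, at 0.0292, and relative to RNY3 and snoRD47, at 0.0326), and over the list alone 0 members passed, or with the round as a block 2, miR-147 and miR-21. Its smallest member was miR-125b-5p at -0.37.

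miRNAs lowered by T cell activation had 18 of 27 assays higher in DC-primed cells, with a median of 0.58 and no call (camera adjusted p = 0.084). They included miR-100 at 2.61 ± 1.23 (SE), miR-181a at 1.31 ± 1.19, miR-150 at 1.07 ± 0.76, miR-26a at 0.68 ± 1.14, miR-29a at -0.46 ± 1.15 and miR-29c at -1.07 ± 1.49. All 10 tested let-7 family assays, from let-7g* at 1.93 to let-7a* at 0.08 with let-7a at 0.56, were higher on the authors' scale, with a median of 0.60 and no call (0.0643). Of the 12 assays of the family, miR-98 and let-7i* were not tested and were lower, at -1.39 and -1.46. Without normalization the medians of these 2 lists and of the NF-kappaB-responsive list were below 0, at -0.75, -0.73 and -0.59, while camera, which compares a list with the other assays, called all 3 up. Camera called the let-7 list without B cell-primed sample 1 (adjusted p = 0.0102), both it and the list lowered by activation without B cell-primed sample 2 (0.0448 each), and the latter without round 2 (0.0374), with a Ct limit of 38 (0.00939) and with no filter (0.00875). Without round 3 it also called these 2 and the NF-kappaB-responsive list. Without DC-primed sample 3 camera called 6 lists, adding these 3 and the imprinted Dlk1-Dio3 locus to the main 2.

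The miR-23/miR-27/miR-24 clusters gave values that depend on the deposited table used. From the authors' dCt, miR-23a differed by -3.42 ± 1.52 (SE) and miR-23b by -3.12 ± 0.82 between DC-primed and B cell-primed cells, and miR-23b passed adjusted over the list alone, at 0.0402 (with the round as a block miR-23a and miR-23b, at 0.00419 and 0.00583). From the deposited Ct minus the same per-sample number, miR-23a differed by -0.66 ± 1.29 (adjusted p = 0.986), with 0.82, -0.12 and -2.66 in the 3 rounds, and miR-23b by -1.79 ± 1.5 (0.971), with 0.17, -0.74 and -4.78. These were the only 2 assays, with 9 of 2060 values compared, whose dCt and Ct differed by more than 0.02 cycles. The gaps were 1, 2, 2.3 or 5 cycles for miR-23a and 1, 2, 3 or 4 cycles for miR-23b, in both directions, and the sources used here give no reason for them. Most moved the dCt difference toward B cell-primed cells. The exceptions were miR-23a in B cell-primed sample 3 and miR-23b in DC-primed sample 3. For example, the miR-23a dCt of DC-primed sample 1 corresponds to a Ct of 24.66, listed as 19.66, and that of B cell-primed sample 2 to 20.04, listed as 22.34. Partners on the same transcripts differed by -0.21 ± 1.55 for miR-27a, 0.29 ± 0.96 for miR-24 and -1.30 ± 1.20 for miR-27b. The star-strand assays of these transcripts were higher in DC-primed cells, up to miR-24-1* at 1.79. The list of 9 assays had a median of 0.13 but a mean of -0.49, and was not called (adjusted p = 0.746, direction down).

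**Figure D3:**
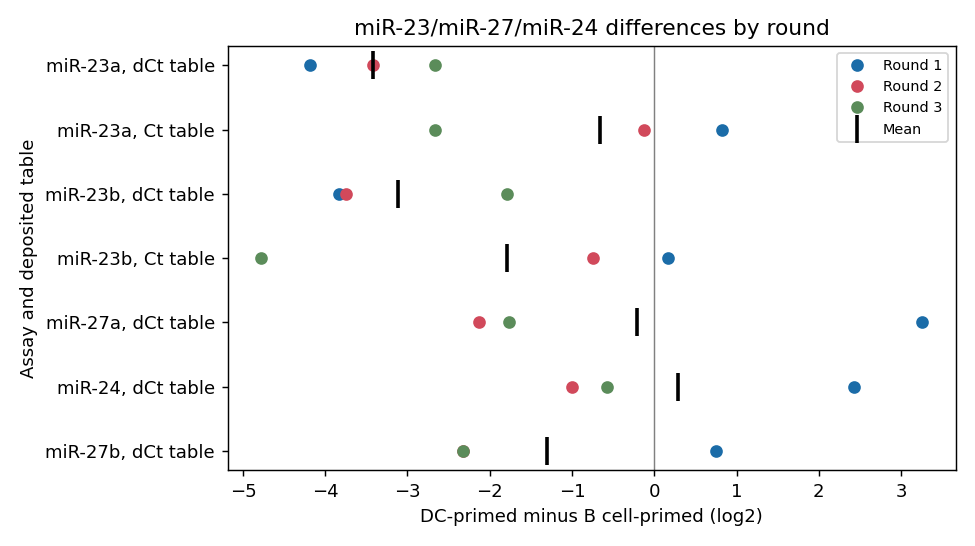
DC-primed minus B cell-primed difference (log2) for miR-23a and miR-23b from the dCt table and from the Ct table, with partner miRNAs from the dCt table; coloured points are rounds and black bars are means. The miR-23a mean is -3.42 from the dCt table and -0.66 from the Ct table, and the points of rounds 2 and 3 coincide for miR-27b.

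The remaining lists were not called. Median differences were 1.04 for the miR-34 and miR-449 family (adjusted p = 0.211), 0.74 for stromal and endothelial markers (0.171), 0.73 for the miR-181 family (0.454), 0.57 for the miR-30 family (0.599), 0.29 for the miR-290 and miR-302 clusters of pluripotent cells (0.599), 0.26 for the mouse Sfmbt2 intron cluster (0.599) and 0.14 for the tissue-restricted list (0.599). They were -0.01 for the miR-15 and miR-16 family (0.874), -0.16 for the imprinted Dlk1-Dio3 locus (0.305), -0.18 for the miR-29 family (0.872) and -0.11 for the miR-200 family (0.972), of which the last 2 had the test direction up. Single members ranged from miR-10a, miR-154 at 1.59, miR-200a at 1.38, miR-34c at 1.34, miR-211 at 1.33 (human-named), miR-297a* at 1.27, miR-302d at 1.17, miR-29c* at 1.16, miR-322 at 1.12 and miR-30e at 0.98 down to miR-758 at -2.37, miR-15b at -1.47, miR-200c at -1.01, miR-30e* at -0.53, miR-467b at -0.36, miR-181d at -0.32 and miR-1 at -0.18. Camera called the stromal and endothelial list higher without DC-primed sample 1 (median 1.17, adjusted p = 0.031) or without both samples of round 1 (1.27, 0.0398). The other smallest members were miR-199a-3p at -0.09, miR-294 at 0.05 and miR-34c* at 0.63. Over the alternatives miR-154 ranged from 0.11 to 2.81 and miR-302d from -0.16 to 2.39. miR-200a was 1.19, 1.56 and 1.38 higher in the DC-primed sample of the 3 rounds.

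The authors' deposited table gives a paired test over the 3 rounds for 345 assays, and 18 had a p under 0.05, where 17.25 are expected by chance. Of these, 5 were higher and 13 lower in DC-primed cells. After Benjamini-Hochberg adjustment of the authors' p-values 0 were under 0.05, and the smallest was 0.0877, for miR-298. The authors' deposited table gives a p of 0.016 for miR-23a and 0.0429 for miR-23b, and the same paired test on the Ct table gave 0.592 and 0.361. Recomputed over the 274 tested assays, the methods' paired t-test called 14 at an unadjusted p under 0.05 and 0 after adjustment.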

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

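The number of changed miRNAs was 0 under 25 of 27 alternatives, with the round as a block among them. It was 0 to 2 when single samples or rounds were left out (2 without DC-primed sample 3) and 5 with that sample left out of filter and fit. The block gave or ended no call of a list or named miRNA over all assays, and its values where it changed counts over lists alone stand beside them. The alternatives added after seeing the data are those so named in the processing summary, plus leaving out rounds for the lists and single samples for detected assays and medians.

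The number of called lists, 2, was 5 without normalization, 1 after quantile normalization, 1 with a Ct limit of 32, 5 with 38, 6 with no filter, 0 with an estimated correlation, 0 with it and the block, 0 by fry, 3 relative to RNY3 and snoRD47, and 2 to 6 with samples or rounds left out. With DC-primed sample 3 or round 3 out of filter and fit it was 6 and 5. The counts with a limit of 38, with no filter and in these last settings include the miR-183/miR-96/miR-182 cluster, lower in DC-primed cells, which then had 4 tested assays in place of 2. The miR-17/miR-92a list kept its direction under all 26 alternatives and its call under 23. The block, the estimated correlation and fry leave every difference unchanged, so they could not change the direction of any list. A constant per sample moves all assays alike, so those scalings hardly test a direction relative to the other assays. Its median of -1.48 was not called with an estimated correlation (adjusted p = 0.347, or 0.583 with the block) or by fry (0.108). Its adjusted p ranged from 7.96e-07 to 0.583. The myeloid list kept its direction under all 26 and its call under 19. It was not called with its median of 1.77 in the same 3 settings (0.347, 0.583 and 0.287), at 1.15 after quantile normalization and at 1.87 with a Ct limit of 32. With samples or rounds left out its median was 0.27 to 2.17, and it was not called without DC-primed sample 1 or without round 1. Its adjusted p ranged from 0.000314 to 0.583. Where fewer assays or samples were tested that is part of the change, and otherwise the cause was not tested.

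The count of miRNAs 2-fold apart in every round, 50, was 101 without normalization, 101 relative to RNY3 and snoRD47, and 28 with a Ct limit of 32, where fewer assays were tested. The difference of the group medians was -1.30 and 1.26 under the first 2, each a constant per sample. Detected assays differed by -51.3 to -5.67 over 8 alternatives. Of 1614 values of named miRNAs under alternatives, 1574 kept their side of the threshold with no change of sign beyond the standard error, 37 uncalled ones changed sign beyond it, and 3 gained a call (miR-805 and miR-100 without DC-primed sample 3). Ct values set the depth: DC-primed sample 3 had 280 of 350 assays below 35.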

Other observations

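The miR-183/miR-96/miR-182 cluster, of which miR-182 is induced by interleukin 2 in helper T cells, had too few tested assays for a list test, with 2 of 4. With a Ct limit of 38 all 4 were tested and camera called the list lower in DC-primed cells, with a median of -1.99 (adjusted p = 0.00159). That call used the preset correlation, and fry and an estimated correlation were not run at this limit. The 4 assays belong to the same cluster and include both strands of the miR-183 hairpin, so they are not 4 independent miRNAs. All 4 assays were lower in the DC-primed sample of all 3 rounds on the authors' scale. The differences were -2.86 for miR-183, -2.19 for miR-182, -1.78 for miR-183* and -1.76 for miR-96. miR-183 differed by -2.97, -2.95 and -2.66 in the 3 rounds, and was not tested because its Ct in DC-primed sample 3 was 35.2. The Ct of miR-96 in that sample was 36.95. miR-182 and miR-183* had adjusted p values of 0.436 and 0.635 in limma. The erythroid list, also with 2 tested of 3 assays, gave 1.31 for miR-451, -0.66 for miR-486 and 0.16 for miR-144, which was not tested.

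Control wells varied more between samples than the miRNA medians did. The mean Ct of cel-mir-67, a nematode sequence whose role the labels do not state, was 18.9, 25.1 and 17.6 in DC-primed samples 1, 2 and 3 and 23.2, 19.6 and 19.3 in the B cell-primed ones. RNY3 differed by -0.89 (exact permutation p = 0.6) and snoRD47 by -1.57 (0.3) on the authors' scale. Assays for the primate cluster had a median Ct of 28.6 to 31.8, against 27.2 to 31.7 for mouse-named assays. Of 80 assays and control RNAs outside the comparison, 5 were below Ct 35 in all 3 DC-primed samples, and 0 of these exceeded every B cell-primed sample.

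A hypothesis set before its test was that guide and star strands of 1 hairpin move together. Over 30 hairpins with both strands tested, the differences correlated at r = 0.549 (Pearson, permutation p = 0.00215), which is consistent with it. Spearman's rho was 0.316 (permutation p = 0.087) and 17 of 30 pairs had the same sign. The pair of miR-18a and miR-18a*, at -3.62 and -3.25, lay farthest from the others, and r was not computed without it. The correlation is across hairpins, which are not independent replicates.

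With 10 possible splits of the 6 samples into 3 and 3, the real one counted among them, no share under 0.05 can be reached. The real split gave 0 calls, as did all 10, with 0 as the highest other. It gave 24 assays at an unadjusted p under 0.05, and 2 of the 10 splits gave as many, the highest other having 48, with DC-primed sample 1 and B cell-primed samples 1 and 2 on one side. It gave 2 called lists, and 7 of the 10 splits gave as many, the highest other having 5. The miR-17/miR-92a list was also called in 1 other split and the myeloid list in 2 others, so calls of these lists recur when the groups are mixed. Among the 4 splits that part all 3 pairs, the other 3 gave 8, 1 and 14 assays and 2, 2 and 1 lists. For the 50 miRNAs at least 2-fold apart in every round, 2 of the 4 arrangements of group within rounds gave as many. These were the real arrangement itself and the swap of round 1, which gave 55.

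For the patterns below, all tests but those of an abundance trend and of an estimated correlation were chosen after the result was seen. The low miR-23a and miR-23b in DC-primed cells may come from how the 2 deposited tables differ. From the Ct table miR-23a differed by -0.657 in place of -3.42, within its standard error of 0. For miR-23b the value of -1.79 ± 1.5 (SE) lay within a standard error of the dCt value of -3.12 and under 2 from 0, which leaves it open. Less of the shared transcripts would lower their partners too. The partners miR-27a, miR-24 and miR-27b differed by -0.409 ± 1.56 (SE) on average. This was 1.84 standard errors from the dCt values of miR-23a and miR-23b, so it cannot be excluded from that mean. The star-strand assays of these transcripts were not in that mean and were higher in DC-primed cells. They were miR-24-1* at 1.79, the human-named miR-23b* at 1.13, miR-27b* at 0.33 and the human-named miR-23a*. The headers name the Ct values as raw, but which values are right for these 2 assays is not stated.

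The lower miR-17/miR-92a list was not explained by the late Ct of DC-primed sample 3 alone, since its median without that sample in filter and fit was -1.67 (camera adjusted p = 0.000122). Late Ct more widely was not excluded, since DC-primed sample 2 was also later than its partner (mean 28.4 against 27.2). In round 1, with means of 26.3 and 26.4, the list median was -0.891. There miR-18a* differed by -1.78, but miR-17 by -0.18 and miR-19b by 2.13. A trend of the difference with abundance was argued against: with a loess trend on the mean level removed, the median was -1.32 (adjusted p = 5.34e-05). Whether members that vary together between samples account for the camera call is not settled by these data. Its adjusted p was 0.347 with an estimated correlation of 0.074 in place of 0.01. That setting also raised camera's unadjusted p for the list raised by T cell activation, from 0.0138 to 0.0548. The estimated correlation of that list was -0.021, below the preset value, so a lost call alone does not point to members that vary together. An effect of the priming cell stays open and was not tested apart from these.

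The higher myeloid list may reflect RNA of the priming dendritic cells, which the labels do not say were removed before extraction. In rounds 1 and 2 miR-223 was higher in the DC-primed sample by 11.1 and 6.55, and miR-146b by 5.97 and 6.17. In round 3 miR-223 differed by -1.49 and miR-146b by -4.09, with the DC-primed sample above Ct 35, where a low level is poorly measured, although the list median in that round was 1.02. miR-146b is not on the myeloid list, but on the list raised by T cell activation and the NF-kappaB-responsive list. Of the 10 names on the myeloid list, 4 are on another fixed list, and T cells express several. Carried-over RNA and a response of the T cells cannot be told apart, because no sample holds dendritic cells alone and the labels name no T cells sorted from them.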
